A study of Mus musculus with 5 samples.

How the data were processed

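Liver RNA of 5 groups of mice was measured as biotin-labelled cRNA on 1 oligonucleotide array per group, each a pool of livers. The number of livers per pool and the composition of the diet are not given in the sources used here. The authors deposited 1 intensity per probe set and array, on a linear scale. The values are MAS5 signals, per the submitters' processing notes, with a 2% trimmed mean close to 500 on every array as tested on the deposited table. No detection calls were used here. The groups were taken from the sample titles; 1 sample, the diet at 1 week, has a source name that conflicts with its title, description and protocols.

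Each array was rescaled to a common 2% trimmed mean, which changed the values very little. The 64 control probe sets were left out of comparisons. Signals were floored at the 40th percentile of all signals (138.9) and taken to log2. Of 22690 probe sets, 20393 have 1 gene symbol in the platform annotation, 691 have several, and 1606 are not listed there and are unnamed here; only those with 1 symbol were used, for 12393 genes. Of the annotated gene identifiers 99.86% matched the gene table of assembly GRCm38.p6, used only for names, and 0 symbols changed. A gene with several probe sets is represented by the one with the highest mean log2 signal, and for part of the named genes the ratios of other probe sets are given beside it. A gene counts as measured in a comparison if it lies above the floor on at least 1 of its 2 arrays. Where 1 side is at the floor, the fold is a bound, the brighter signal over the floor, written as at least N-fold.

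With 1 array per group no test was possible and no p-value was made. Comparisons were the diet against chow at 10 weeks and at 1 week, atorvastatin on the diet against the diet, atorvastatin on the diet against chow, and chow at 10 weeks against chow at 1 week as background. Genes past a 2-fold ratio were counted. For 35 gene lists of pathways and cell types the median log2 ratio was set among 10000 random lists of the same size matched on mean signal in 20 bins, and a list stands apart below the percentile of 2.5 or above 97.5; at least 3 measured members were required. Of 583 listed members 505 have a named probe set here. The percentile describes these arrays and does not test the conditions. Grouping, lists, comparisons and the rule for named genes were fixed before the data were examined. That rule takes, per main comparison, the 10 genes per direction with the largest log2 ratio and both signals above the floor, up to 3 bounds per direction, up to 4 members of each list described, 18 preset genes of which 15 have a named probe set here, and the 10 genes per direction past 2-fold at both diet times. Loci with clone names of the Rik, Gm, LOC, BC and AI types were passed over. AY036118, a sequence identifier of another type, was kept. Orm2 and Nr1d2, named to complete counts, lie outside the rule and were chosen after their values were seen.

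Noise for simulations came from the spread of the chow pair by signal level. That pair also differs in time on chow and in age, so this spread is not noise alone. A test on simulated data for the diet at 10 weeks covered 9065 genes, with 50 genes changed per fold. The changed genes were drawn only from those with a mean log2 signal above that of 2 times the floor. The 2-fold rule took 50.0% of genes changed by 2-fold, 92.0% at 3-fold, 98.0% at 4-fold and 96.0% at 8-fold. It also took 3.42% of unchanged genes. The rates for changed genes do not cover dimmer genes. Of 200 unchanged simulated lists of 15 genes 3.00% stood apart, and of 200 lists shifted by 0.5 on the log2 scale 92.0%, over 8865 genes. Between the 2 chow arrays themselves 5 of 33 lists stood above and 4 below the random lists, a larger share than in the simulation. Alternatives were no rescaling, quantile normalization, cyclic loess, floors at the 20th and 60th percentile, a pseudocount in place of the floor, the mean of all probe sets, leaving out the x and s probe sets where a gene has others, rules of 1.5-fold and 3-fold, and the mean of both chow arrays as reference. The 1-week chow array as reference for the diet at 10 weeks was added after seeing the data, as was the mean of both chow arrays for single genes. Tests prepared for higher cholesterol synthesis with atorvastatin were not run, because that list did not stand apart.

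On quality, the 3' to 5' signal ratio of the Gapdh control lay between 0.783 and 1.01 and that of beta-actin between 1.17 and 1.73. The geometric mean of 9 spike-in probe sets was 5.47 times that of the 1-week chow array on the 10-week chow array, 1.83 times on the 10-week diet array, 2.03 times with atorvastatin and 1.11 times on the 1-week diet array. Spearman correlations between arrays lay between 0.911 and 0.946, and no pair was a duplicate. The 18S ribosomal RNA control signal of the atorvastatin array was 6.38 to 31.9 times that of the other arrays. The labels give no batch. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.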

Results

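RNA from mouse liver was measured on 5 oligonucleotide arrays, each hybridised with a pool of livers from 1 group of C57B/L mice. The mice were 8 weeks old and had 2 weeks of acclimation. A pair of groups was kept for 1 week on standard chow or on an atherogenic diet, which is a feed used to raise blood cholesterol and promote artery disease. The other groups were kept for 10 weeks on chow, on the atherogenic diet, or on the diet with atorvastatin for the last 3 weeks. Atorvastatin is a statin, an inhibitor of the rate-limiting step of cholesterol synthesis. There are no replicates: each group is 1 array, so no test or p-value was made, the number of arrays limits the precision, and all values describe these pools. Genes are named by a fixed rule, which takes the largest ratios past 2-fold, and preset genes and members of the lists described whether past 2-fold or not. The 2 chow arrays, which share their diet but differ in time on it and so in age at sampling, serve as background. Between them 222 of 9087 genes were higher and 177 lower at 10 weeks by at least 2-fold, 4.39% in all. In this pair 95% of genes lay within 1.83-fold to 2.11-fold, depending on the signal quartile. The 1-week diet sample is labelled chow in its source name and atherogenic in its title, description and protocols. It was grouped by its title.

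After 10 weeks on the atherogenic diet, genes of fatty acid and triglyceride synthesis were higher than on chow at 10 weeks. Of 20 measured members 10 were at least 2-fold higher and 0 lower, with a list median log2 ratio of 1.00. These included Thrsp, a regulator of lipogenesis (log2 2.23), Acacb, an acetyl-CoA carboxylase (2.07), Elovl6, a fatty acid elongase (1.77), Pnpla3 (1.69), fatty acid synthase Fasn (1.60) and the sterol regulatory transcription factor Srebf1 (1.10). The fatty acid binding protein gene Fabp5 had a signal of 542 on chow and 4497 on the diet, 8.30-fold higher. Cholesterol synthesis enzymes had a median of 0.43, with 3 of 16 members past 2-fold higher, Msmo1 (3.01), Fdft1 (1.5) and Fdps (1.23), and 1 lower, Cyp51 (-1.21). With the mean of all probe sets only Msmo1 of these 4 was past 2-fold, with Fdft1 at 0.81, Fdps at 0.62 and Cyp51 at -0.19. Lower signals were found for Gsta2, a glutathione S-transferase (-2.52), the p21 gene Cdkn1a (-2.19), the acyl-CoA thioesterase gene Acot1 (-2.04), the urea cycle gene Asl (3.99-fold lower) and the pyruvate dehydrogenase kinase gene Pdk4 (-1.92).

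Of 34 lists, 8 stood above and 4 below the central 95% of random lists for the diet at 10 weeks, against 5 and 4 of 33 between the chow arrays, which share their diet. At 10 weeks of chow against 1 week the 5 were hepatocyte markers (0.51), cholesterol synthesis (0.50), glutathione, NRF2 and metallothionein genes (0.31), acute phase (0.30) and fatty acid and triglyceride synthesis (0.28). The 4 were macrophage and Kupffer cell markers (-0.48), endothelial markers (-0.40), sterol uptake and SREBP2 regulation (-0.37) and mitochondrial respiration (-0.13). The 10-week chow array had spike-in signals 5.47 times those of the 1-week chow array, against 1.11 to 2.03 times on the diet arrays, and the highest 3' to 5' ratio of beta-actin (1.73, others 1.17 to 1.61). In all, 331 of 9232 genes were higher and 283 lower by at least 2-fold on the diet at 10 weeks, 6.65% against 4.39% for the chow pair. Both comparisons use the 10-week chow array, so its deviations enter both with opposite signs. Of genes measured in both, 73 lower on the diet were higher in the chow pair, and 54 higher on the diet were lower there. Independent lists would share 7.12 and 5.49, and the Pearson correlation was -0.46. A shared array gives such opposite ratios without a diet change. The 10-week and 1-week diet arrays, which also share their diet, differed by at least 2-fold for 768 of 9086 genes. That is more than the 614 for the diet against chow, so the diet count does not exceed both same-diet pairs. With the 1-week chow array in place of the 10-week chow array, an alternative chosen after seeing the data but before this count was made, 330 were higher and 252 lower, 582 in all against 399 for the chow pair. Those arrays differ in time on the feed and in age as well as in diet. With the mean of both chow arrays 231 were higher and 167 lower, counts that cannot be set against those of the chow pair, where each side is 1 array. Against random lists matched on signal, the percentile of the median was 100 for fatty acid and triglyceride synthesis and 99.8 for cholesterol synthesis. Other genes at the top of the size ranking were Serpina12 (3.01), the sterol transfer gene Stard4 (2.42), Fen1, a flap endonuclease (2.27), Neat1, a long noncoding RNA (2.21), and Rsu1 (2.02). Dbp was at least 8.86-fold higher, Sfrp1 at least 6.57-fold and Krt23 at least 3.98-fold, since their chow signals were at the floor; the other Sfrp1 probe set gave 0.35. At the lower end stood AY036118 (-3.15), the nicotinamide methyltransferase gene Nnmt (-2.43), Wdtc1 (-2.25), the clock gene Arntl (-1.92) and the metallothionein gene Mt1 (-1.90, with 0.89 from its other probe set). Nfic was at least 7.25-fold lower, Rrs1 at least 5.13-fold and Nrip1 at least 5.0-fold. Against the 1-week chow array Neat1 had a log2 ratio of 0.14, Acacb 0.81, Apoa4 0.37, Sfrp1 0.84, Mt1 -0.97, Mt2 -0.23, Nrip1 -0.69 and Cyp51 0.30, none of them past 2-fold.

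Sterol uptake and SREBP2 regulation had a median of 0.44 at 10 weeks of diet (percentile 99.5), with Stard4 as the 1 of 9 members past 2-fold. LXR targets and sterol export had a median of 0.40 (percentile 99.5) with 0 of 10 members past 2-fold; the sterol exporter genes Abcg5 and Abcg8 had 0.75 and 0.56. Interferon-stimulated genes had a median of 0.60 (percentile 99.96), with Psmb9 at 0.94, Irf1 at 0.89, Ifit1 at 0.85 and 1 of 13 members, Rsad2, past 2-fold lower (-1.06, and -0.055 with the mean of all probe sets). The circadian clock list had 4 of 14 members higher and 2 lower (median 0.52, percentile 99.7), among them Nr1d1 (2.29) and Nr1d2 (1.21), both repressors of the clock loop. With the mean of all probe sets the clock median at 10 weeks was 0.17 (percentile 83.1), no longer apart. PPAR alpha targets and fatty acid oxidation had a median of -0.42 (percentile 0.12), with 3 of 23 members lower: Acot1, Pdk4 and the hormone gene Fgf21, at least 4.27-fold lower. Glutathione, NRF2 and metallothionein genes had a median of -0.38 (percentile 0.50), with 3 of 19 lower, Gsta2, Mt1 and Mt2 (-1.31), and Gstm3 higher (1.41). Lipoproteins had a median of -0.46 (percentile 0.54), with Apob at -1.75 and Apoa4, an apolipoprotein of lipid transport, at 1.71. With the 1-week chow array the medians were 0.08 for sterol uptake, -0.14 for PPAR alpha targets, -0.10 for the glutathione list and 0.08 for lipoproteins, all inside the central 95% of random lists, as they were with the mean of both chow arrays (0.20, -0.13, -0.22 and -0.15). Lipoproteins were also inside with quantile normalization (-0.17) and cyclic loess (-0.19). In bile acid synthesis (median -0.06, percentile 45.6) Cyp8b1, the sterol 12-alpha-hydroxylase gene, had -1.34, Cyp39a1 -1.25 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, -0.66.

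Macrophage and Kupffer cell markers were higher on the 10-week diet array, with a median of 0.66 (percentile 100) and 4 of 20 members past 2-fold: Cd5l (1.24), Clec4f (1.14), Tyrobp (1.13) and Adgre1 (1.07). The macrophage marker Cd68 had 0.73. On the 10-week chow array the same list lay below the 1-week chow array, with a median of -0.48. Against the 1-week chow array the 10-week diet median was 0.19 (percentile 88.3), and Cd5l had 0.19, Clec4f 0.13, Tyrobp 0.23 and Adgre1 0.42. Extracellular matrix and fibrosis genes had a median of 0.34 (percentile 99.0), with Anxa2 (1.20), Col3a1 (1.02) and Lgals1 (1.00) past 2-fold. This list no longer stood apart against the 1-week chow array (median 0.06), with quantile normalization (0.26, percentile 96.7) or cyclic loess (0.26, percentile 97.0), or with the mean of all probe sets (0.14), where Anxa2 had 0.40, Col3a1 0.51 and Lgals1 0.63. Hepatocyte markers had a median of -0.46 (percentile 1.36), with Arg1 at -1.06; the median was -0.09 with quantile normalization, -0.22 with cyclic loess, -0.19 with the mean of both chow arrays and 0.12 against the 1-week chow array, none of them apart. Endothelial markers had a median of 0.28, with Cdh5 (2.02) and Oit3 (1.66) past 2-fold, Lyve1 at least 3.44-fold higher, and a percentile of 91.4. Medians of the other cell-type lists were 0.39 for neutrophils, 0.41 for lymphocytes, 0.21 for stellate cells, -0.18 for MHC class II, 0.36 for red blood cells and 0.43 for fat and pancreas. All of these lay inside the central 95% of random lists. Endothelial markers stood apart, at 0.44, with the floor at the 60th percentile (percentile 99.3) and without the x and s probe sets (percentile 98.9), and neutrophil markers with the mean of all probe sets (0.39, percentile 98.1) and the mean of both chow arrays (0.55, percentile 99.1).

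**Figure D1:**
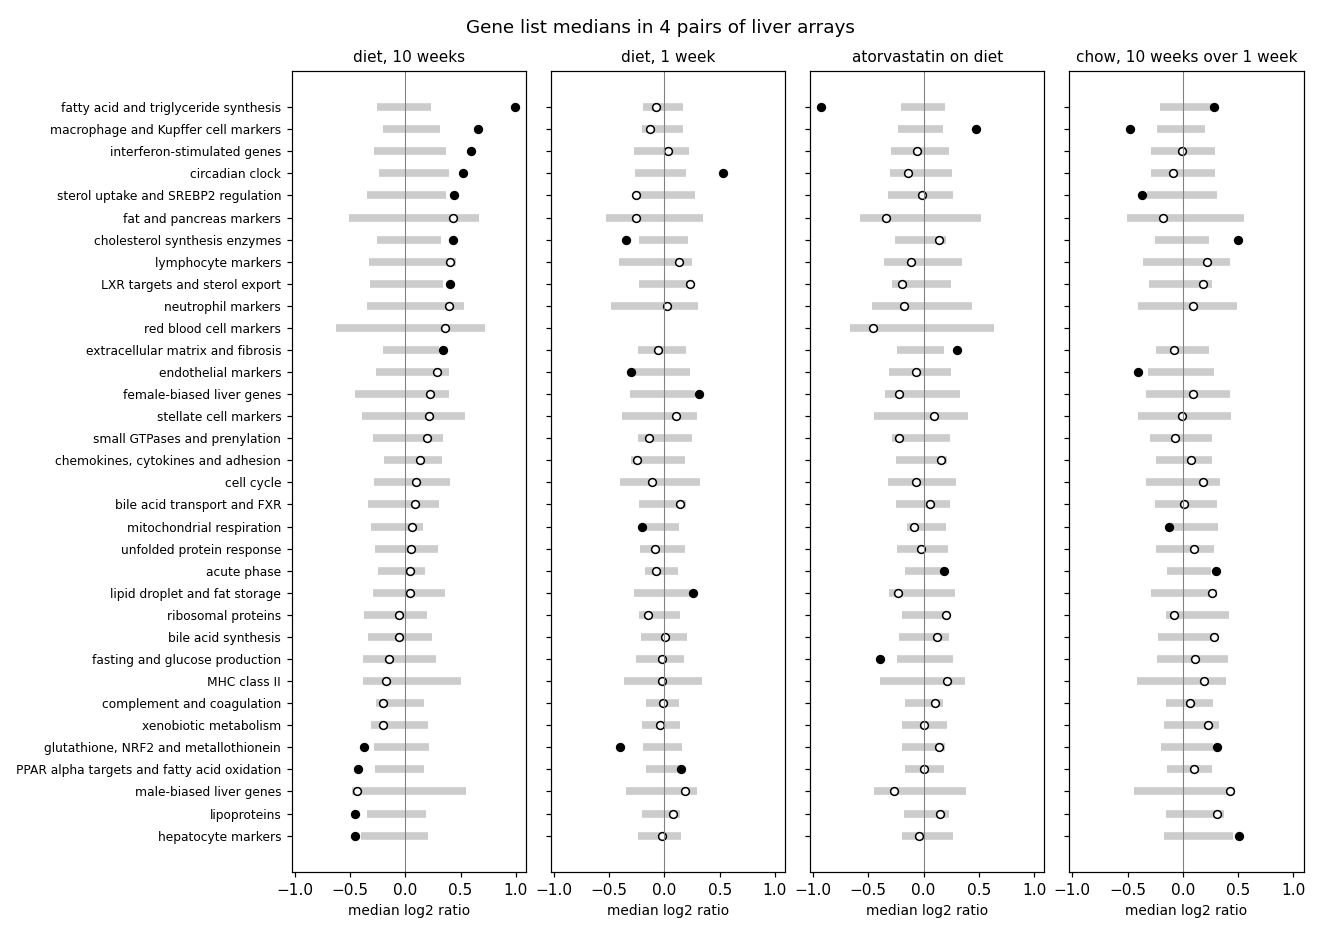
Median log2 ratio (x axis) of each gene list (y axis) in 4 pairs of arrays; filled points lie outside the central 95% of random lists, and grey bars span 2 SD either side of the random lists' median. Fatty acid and triglyceride synthesis lies at 1.00 for the diet at 10 weeks and at -0.93 with atorvastatin.

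After 1 week on the diet, the clock list stood apart, while the medians of the cholesterol synthesis and glutathione lists were lower than on chow. Nr1d1 had a log2 ratio of 1.70 and Nr1d2 1.15, Dbp was at least 2.98-fold higher and Cry2 at least 2.54-fold, while Nfil3, a transcriptional repressor, had -1.79 and Arntl -1.29. Of 14 clock genes 4 were higher and 2 lower (median 0.53, percentile 100); with the floor at the 20th percentile the median was 0.16 and no longer apart (percentile 95.1), and with the floor at the 60th percentile Dbp had 0.56 and Cry2 0.33. Cholesterol synthesis enzymes had a median of -0.34 (percentile 0.10) with 0 of 16 past 2-fold; Hsd17b7 had -0.82, Fdps -0.81, the squalene epoxidase gene Sqle -0.78 and Lss -0.66. Glutathione, NRF2 and metallothionein genes had a median of -0.41 (percentile 0.00), with Gsta2 (-1.5) and Gstm3 (-1.17) past 2-fold. Both lists also stood apart between the chow arrays, where cholesterol synthesis differed by more (0.50) and the glutathione list by less (0.31). The clock list did not (-0.09, percentile 27.1), though a median can hide members that move both ways. Of its 13 members measured there 5 were positive and 8 negative, with 1 past 2-fold, Nfil3 (-1.31). Cyp2b10, a drug-metabolising cytochrome, had -1.71 and its other probe sets -1.73 and -1.37.

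Of 33 lists 4 stood above and 4 below the random lists at 1 week, no more than the 5 and 4 between the chow arrays. At 1 week 93 of 8798 genes were higher and 109 lower by at least 2-fold, 2.30%, which is below the 4.39% of the chow pair. With cyclic loess the split was 136 higher and 98 lower. The largest values were those of Malat1, a long noncoding RNA (2.04, other probe sets -0.59 to 0.49), Nfib (1.71, others -0.15 to 0.36), Samhd1 (1.57, others -0.26 to 2.01), Naglu (1.56), Rps4l (1.53), Otub1 (1.5, other -0.18), the stress-response gene Trib3 (1.49), Cttn (1.38, others -0.20 to 0.27) and the heme synthesis gene Cpox (1.38, other 0.25). Pmf1 was at least 4.32-fold higher, Dedd at least 3.65-fold (other probe sets -0.44 and 0.29) and Hectd3 at least 3.63-fold. On the lower side stood Casr (-1.65), Nck1 (-1.65), Btc (-1.61), the immediate early gene Fos (-1.57), Foxf1 (-1.54), Mvb12b (-1.54), Rnf4 (-1.53, other 0.30) and Rsrp1 (-1.53, others 0.11 and 0.29). Arhgef40 was at least 3.54-fold lower, Polr3d at least 3.41-fold and Neurod2 at least 2.79-fold. Cyp7a1 had -1.05, with -2.18 from its other probe set, and the adhesion gene Vcam1 had -1.30, with -0.17 and 0.51 from others.

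Among the other lists at 1 week, PPAR alpha targets and fatty acid oxidation had a median of 0.15 (percentile 98.3), with Pdk4 as the 1 of 23 past 2-fold (-1.01) and Acaa1a at 0.61. Lipid droplet and fat storage genes had 0.25 (percentile 98.3), with the lipid droplet gene Cidec at 1.27. Female-biased liver genes had 0.31 (percentile 98.4) with 0 of 6 past 2-fold. Endothelial markers had -0.30 (percentile 1.36) and mitochondrial respiration -0.20 (percentile 0.84), each with 0 members past 2-fold. Fatty acid and triglyceride synthesis had -0.07 (percentile 25.6), with Fasn at -0.15 and Srebf1 at 0.29. Macrophage and Kupffer cell markers had -0.13 (percentile 11.8). With quantile normalization PPAR alpha targets (0.12), female-biased genes (0.27) and mitochondrial respiration (-0.16) were no longer apart, at medians within their spread of those above. The mean of all probe sets ended the calls of endothelial markers (-0.24) and mitochondrial respiration (-0.091), and that of lipid droplet genes ended with cyclic loess (0.25), a pseudocount (0.18) and both other floors (0.16 each).

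Between both diet times, 14 genes were at least 2-fold higher and 7 lower in each comparison, where independent lists of these sizes would share 3.26 and 3.27. The diet comparisons share no array. Genes higher at both times included Malat1, Nr1d1, Dbp, Krt23, Ngef, Apoa4, Phlda1, Plin3, Nfib and Il17rc, with Apoa4 at 1.71 and 1.24 and Phlda1 at 1.38 and 1.17 for 10 weeks and 1 week. The lipid droplet coat gene Plin3 had 1.35 and 1.16. At 10 weeks other probe sets of Malat1 ran from -0.28 to 1.26 and those of Nfib from -0.34 to -0.13. Against the 1-week chow array the 10-week ratios of Apoa4 (0.37), Malat1 (0.97), Phlda1 (0.41) and Nfib (0.76) were inside 2-fold. Lower at both times were Gsta2, Arntl, AY036118, Cdkn1a, Ndufb1, Scaf8 and Pdk4, with Cdkn1a at -2.19 and -1.03, and Scaf8 at -1.02 at 10 weeks (other probe set -0.29). In opposite directions, 9 genes were higher at 10 weeks and lower at 1 week, and 9 the other way round, where independent lists would share 3.78 and 2.82. Across 8423 genes, which are not independent replicates, the log2 ratios had a Pearson correlation of -0.07 and a Spearman correlation of -0.09. The diet ratio was at least 2-fold higher at 10 weeks than at 1 week for 699 genes and lower for 537, a difference that was not tested.

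With atorvastatin on the diet, 3 acute phase genes, Saa1, Saa2 and Lcn2, were far higher than on the diet alone, and lipogenic genes were lower. The serum amyloid genes Saa1 and Saa2, acute phase proteins of the liver, had log2 ratios of 4.40 and 3.95; the Saa1 signal was 19553 with atorvastatin and between 754 and 1095 on the other arrays. The 18S ribosomal RNA control probe sets of that array also stood apart, with a geometric mean signal of 13944 against 437 to 2185 on the others. The iron-binding protein gene Lcn2 had 2.86, Saa3 1.49 (0.74 with the floor at the 60th percentile) and Orm2 1.33, making 5 of 24 acute phase genes past 2-fold higher and 0 lower; 9 of the 24 had negative ratios, and the list median was 0.18 (percentile 98.1). Fatty acid and triglyceride synthesis had a median of -0.93 (percentile 0.00), with 9 of 20 members past 2-fold lower, among them Fasn (-1.75), Elovl6 (-1.74), Acly (-1.69) and Pnpla3 (-1.66), and Acacb at least 6.13-fold lower. Cholesterol synthesis enzymes, the pathway of the drug's target, had a median of 0.14 (percentile 92.9), with Cyp51 at 1.24, Mvk at least 2.45-fold higher, Msmo1 at 0.98 and Hmgcs1 at 0.81 (other probe sets -0.63 to -0.12).

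Of 34 lists 3 stood above and 2 below the random lists with atorvastatin, fewer than between the chow arrays. With atorvastatin 200 of 9293 genes were higher and 197 lower by at least 2-fold, 4.27%, close to the 4.39% of the chow pair. Nnmt (2.56), Hnrnpab (2.46, other probe sets 0.58 to 0.83), the lysozyme gene Lyz1 (2.39, others 0.88 and 1.34), AY036118 (2.37), the complement gene C8b (1.94), Apob (1.83) and Jup (1.78) were among the largest higher values. Against chow at 10 weeks the atorvastatin array had, in the same order, 0.14, 0.93, 3.77, -0.78, 0.30, 0.08 and 1.20. Where these values are small, a deviation of the 10-week diet array alone stays open. Marco, a macrophage scavenger receptor gene, was at least 8.14-fold higher, Atg2a at least 5.76-fold and Timp3 at least 5.19-fold (other probe sets 0.17 and 0.51). Among the lower genes were Fabp5 (-2.59), Cdh5 (-2.40, other probe set -0.48), Fen1 (-2.19), Ampd2 (-2.04, other 0.26), Ctnnd1 (-2.03), Rgs16 (-2.01), the water channel gene Aqp8 (-2.0), Arhgap9 (-1.98, other -0.27), Fitm1, a lipid droplet gene (-1.83), and Cnot8 (-1.76, other -0.28). Set against chow at 10 weeks these had, in order, 0.46, -0.38, 0.08, -1.10, -0.21, -0.72, -0.09, -1.41, -0.23 and -1.45. The same limit holds for the small values here. Kansl1 was at least 5.25-fold lower and Add3 at least 4.46-fold (other probe sets -0.70 and -0.25). Scd1 had -0.49, and -1.94 from its other probe set; at 10 weeks of diet these were 0.12 and 2.38.

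Macrophage and Kupffer cell markers were higher with atorvastatin (median 0.47, percentile 100), with Marco and Lgals3 (1.55) past 2-fold and Cd68 at 0.28. Extracellular matrix and fibrosis genes had a median of 0.30 (percentile 99.8) with 3 of 22 past 2-fold, Col1a1, Col5a2 and Tgfb1, each a bound from a signal at the floor. With the floor at the 60th percentile the list no longer stood apart (median 0.080, percentile 86.9), and Col1a1 had 0.049, Col5a2 0.11 and Tgfb1 0.040. Fasting and glucose production genes had -0.40 (percentile 0.07) with 0 of 11 past 2-fold, including Gys2 at -0.83 and G6pc at -0.57. Endothelial, neutrophil and hepatocyte markers had medians of -0.07, -0.18 and -0.04. Small GTPases and prenylation genes had -0.23 (percentile 5.72). Cyp8b1 had 1.00, Cyp7a1 0.57, Abcg5 -0.62, Abcg8 -0.71 and Srebf1 -0.96.

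The diet and atorvastatin comparisons at 10 weeks share the array of the diet alone. Of the genes higher on the diet 77 were lower with atorvastatin, and of those lower on the diet 73 were higher. Independent lists would share 7.30 and 5.14, and simulated unchanged groups with the shared array gave 64.1 and 13.5 genes. The floor and the rule for measured genes favour the first direction. A dim gene can rise above the floor on the shared array but cannot fall below it. The observed counts follow the same rule, and how much of the difference between directions it explains was not tested. The simulated spread is that of the chow pair, which also differs in time and age and so is not noise alone. Its log2 ratios had an SD of 0.48, against 0.41 for the diet at 1 week. The Pearson correlation across genes was -0.51 against -0.54 in the simulation, and the covariance -0.13 against -0.11, a difference of -0.020. The shared array could not be split, so part of the excess may come from it. Genes chosen at 1 week, on arrays that the atorvastatin ratio does not use, had median atorvastatin ratios of -0.02 for the 85 higher genes (percentile 61.2) and 0.01 for the 106 lower genes (percentile 76.1). These medians turned on the setting: the higher set had 0.12 with the floor at the 60th percentile (percentile 97.9) and 0.13 with a pseudocount (percentile 98.6), and the lower set 0.10 with quantile normalization (percentile 97.6). Genes chosen at 10 weeks had -0.58 for 331 higher genes and 0.60 for 261 lower genes, with median diet ratios of 1.19 and -1.24. They were chosen on the array that the atorvastatin ratio shares, so medians of these signs arise without a drug effect. In 100 simulations in which only the spread of the chow pair separated the diet array from the atorvastatin array, the medians were -0.37 and 0.21. Both observed medians lay outside the simulated ranges, which were -0.44 to -0.29 and 0.12 to 0.28. A spread above noise alone would enlarge the simulated medians, not shrink them. The simulated noise was independent between genes, so a deviation of the 10-week diet array or pool that many genes share stays open. These values therefore do not show a reversal by the drug.

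Set against chow at 10 weeks, the atorvastatin array had 282 of 9244 genes higher and 227 lower by at least 2-fold, and of 33 lists 7 stood above and 5 below the random lists. Macrophage and Kupffer cell markers had 11 of 23 members past 2-fold higher (median 0.73), among them Cd5l (2.11), Lgals3 (2.09) and Tyrobp (1.84). This list was low on the 10-week chow array, at -0.48 against the 1-week chow array. Other cell types and tissue lists stood apart with it: hepatocyte markers had -0.39 with 11 of 11 members negative (percentile 0.88), endothelial markers 0.33 (percentile 98.0) and extracellular matrix and fibrosis 0.58 (percentile 100). Fatty acid and triglyceride synthesis had a median of -0.15 (percentile 13.0). Msmo1 of cholesterol synthesis had 3.99, and that list a median of 0.50. Acute phase had a median of 0.20, with 5 of 24 members higher and 1 lower. The other lists apart were interferon-stimulated genes (0.41), ribosomal proteins (0.20), PPAR alpha targets (-0.33), glutathione, NRF2 and metallothionein genes (-0.39), cell cycle (-0.36) and male-biased liver genes (-0.96).

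**Figure D2:**
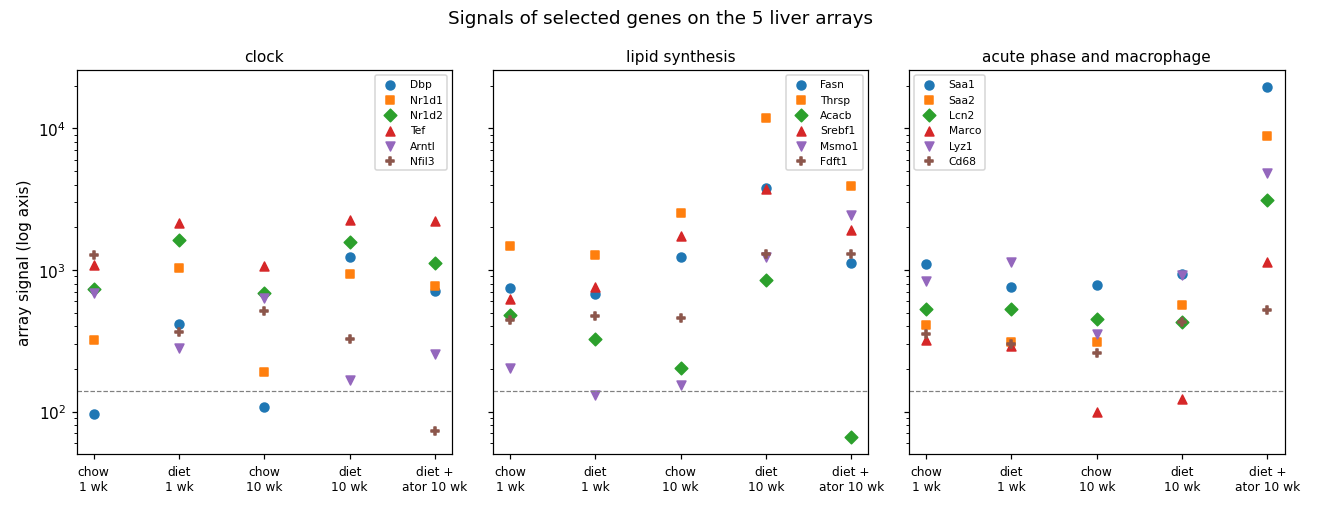
Array signal on a log axis (y axis) of 18 genes on the 5 arrays (x axis), 1 point per gene and array; the dashed line is the floor at 138.9. Saa1 stands at 19553 with atorvastatin, Nr1d1 lies between 772 and 1039 on the 3 diet arrays and at 190 and 321 on the chow arrays.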

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

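Tests of the clock and fatty acid synthesis patterns were chosen only after the result was seen; those of the macrophage pattern were written before. The 18S ribosomal RNA control probe sets, which no comparison uses, had a geometric mean signal of 13944 on the atorvastatin array against 737 and 2185 on the chow arrays, 1002 on the 10-week diet array and 437 on the 1-week diet array. The diet median of cholesterol synthesis enzymes was 0.78 higher at 10 weeks than at 1 week, with opposite signs at each time (0.43 and -0.34). PPAR alpha targets and fatty acid oxidation differed by -0.57, from -0.42 at 10 weeks to 0.15 at 1 week. Among genes named by size or preset, with opposite diet ratios past 2-fold, the difference of 10 weeks minus 1 week was 2.83 for Add3, -2.91 for Dedd and -2.97 for Samhd1, whose other probe sets differ in sign at 1 week as do those of Dedd. Genes named only as list members were not scanned. Of these, Gstm3 was higher at 10 weeks and lower at 1 week, each past 2-fold, though not at 1 week with the mean of all probe sets. None of these differences between times was tested.

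Clock genes were past 2-fold in both diet comparisons, which share no array. Of 13 clock genes measured at both times 4 passed 2-fold the same way at each; the list was singled out after all lists were seen, and in 10000 draws of random matched lists for all 33 lists no list had more than 3, which argues against noise that is independent between genes. At 1 week Dbp was at 0.56 with the floor at the 60th percentile and Arntl at -0.97 with a pseudocount, and Nr1d2 was not run under the alternatives. Genes that peak with Dbp exceeded those that peak with Arntl by a median of 1.80 at 10 weeks and 2.13 at 1 week, and by 0.26 between the chow arrays. A different phase of the daily cycle at sampling and a shift of the clock by the diet itself cannot be told apart, since hours of sampling are not given in the sources used here and each diet pool has 1 chow partner.

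Fatty acid and triglyceride synthesis genes were higher on the 10-week diet array and lower with atorvastatin, ratios that share this array; without it, atorvastatin against chow gave -0.15 (percentile 13.0), so a deviation of this single array or pool stays open for both. Against the 1-week chow array the list's percentile was 100 (median 1.04), which argues against noise of the 10-week chow array, though those arrays also differ in time on the feed and in age. A fed against fasted difference between the pools stays open, because 7 fasting-induced genes had a median of -0.037 with atorvastatin (SD 0.17 over random lists). The preset fasting and glucose production list had -0.40 with atorvastatin (SD 0.13, 10 of 11 members negative), which argues against a more fasted atorvastatin pool but leaves it open, since the list also holds genes of glucose storage and transport. On the diet at 10 weeks against chow all 7 fasting-induced genes were lower, a direction that a less fasted diet pool would give. Fgf21 was at least 4.27-fold lower, with G6pc at -1.43, Pck1 at -0.98, Igfbp1 at -0.81, Irs2 at -0.58, Ppargc1a at -0.52 and Cpt1a at -0.16. An effect of diet and drug stays open too, untested.

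Macrophage and Kupffer cell markers were higher at 10 weeks of diet. Their median exceeded that of endothelial markers by 0.38, below 2 SD of that gap over random lists (SD 0.21), so a lower share of hepatocyte RNA, which would raise both, remains a possible explanation, and endothelial markers stood apart, at 0.44, with the floor at the 60th percentile and without the x and s probe sets. Read against 2 SD of the macrophage list alone (SD 0.13) the gap would argue against it, and the choice of SD was not settled before the test. Against red blood cell markers the gap was 0.30 (SD 0.36) with 3 genes measured, too few to decide on blood left in the tissue. Against the 1-week chow array the diet medians were 0.19 for macrophage, 0.086 for endothelial and 0.12 for hepatocyte markers, none of them apart. Between the chow arrays, which share their diet, these medians were -0.48, -0.40 and 0.51 at 10 weeks against 1 week, all apart. A deviation of the 10-week chow array or pool therefore stays open too, though the arrays compared here also differ in time on the feed and in age. An effect of the diet on macrophages stays open as well, untested.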

How the results depend on the processing

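The 1-week chow array as reference, and the mean of both chow arrays for single genes, were chosen only after the data were seen; the other alternatives were not. Leaving out a replicate was not possible with 1 array per group. With no rescaling, all results run under it moved by less than their spread. List medians of the chow pair and of atorvastatin on the diet against chow were not run under any alternative. Fatty acid and triglyceride synthesis stood apart at 10 weeks and with atorvastatin under every alternative run. Among values of list medians under the alternatives, 182 kept their call and moved by less than their spread, and 11 kept it and moved by more; among ratios of named genes these were 952 and 110. Another 31 values of list medians lost the call and 11 gained one, as did 135 and 20 ratios of named genes. Lists that gained a call at 1 week were LXR targets with cyclic loess (0.26), chemokines, cytokines and adhesion with a pseudocount (-0.25) and cell cycle without the x and s probe sets. With atorvastatin they were lipoproteins without the x and s probe sets, and the circadian clock (-0.33) and red blood cell markers (-1.38) with the floor at the 20th percentile. Before the 10-week diet count against the 1-week chow array was made, noise of the 10-week chow array was set to predict at most the 399 genes of the chow pair, and the count was 582. These arrays also differ in time on the feed and in age, which can raise the count with or without such noise, so it does not decide. The mean of all probe sets took Anxa2, Col3a1, Cyp51, Fdft1, Fdps, Lgals1, Malat1, Mt1, Nfib, Nfic, Rsad2, Scaf8 and Sfrp1 inside 2-fold for the diet at 10 weeks. It did so for Arhgef40, Btc, Casr, Cpox, Cttn, Dedd, Gstm3, Malat1, Mvb12b, Nfib, Otub1, Rnf4, Rsrp1, Samhd1, Scaf8 and Vcam1 at 1 week, and for Acly, Ampd2, Arhgap9, Col1a1, Col5a2, Hnrnpab and Timp3 with atorvastatin. The floor at the 60th percentile took Cyp51, Il17rc, Krt23, Nfib, Ngef, Per1, Pnpla3 and Scaf8 inside 2-fold at 10 weeks, Arhgef40, Btc, Cidec, Cry2, Dbp, Dedd, Foxf1, Hectd3, Il17rc, Krt23, Naglu, Ndufb1, Neurod2, Ngef, Otub1, Polr3d and Rps4l at 1 week, and Col1a1, Col5a2, Saa3 and Tgfb1 with atorvastatin. Low signals limit what can be read, since fewer dim genes pass the rule under a higher floor. Values that moved by more than their spread (SD of the chow pair or of random lists), or by over 1.5 times for counts, follow, and the cause was not tested. With quantile normalization, the atorvastatin median of the 1-week diet genes was 0.072 for the higher set (percentile 92.0) and 0.10 for the lower set (percentile 97.6). At 10 weeks the diet medians became PPAR alpha targets and fatty acid oxidation -0.20, lipoproteins -0.17, acute phase 0.17, complement and coagulation -0.083, hepatocyte markers -0.090, xenobiotic metabolism -0.028 and fasting and glucose production 0.043. At 1 week they became acute phase 0.0068 and hepatocyte markers 0.10. With cyclic loess, the atorvastatin median of the 1-week diet genes was 0.083 for the lower set (percentile 95.2). Diet list medians at 10 weeks became bile acid transport and FXR -0.14, PPAR alpha targets and fatty acid oxidation -0.27, lipoproteins -0.19, complement and coagulation -0.071, hepatocyte markers -0.22, xenobiotic metabolism -0.053, fasting and glucose production 0.035 and mitochondrial respiration 0.19. With the floor at the 20th percentile, the genes past the rule numbered 884 higher and 738 lower for the diet at 10 weeks, 332 higher and 498 lower for the diet at 1 week, 687 higher and 626 lower for atorvastatin, 645 higher and 653 lower for the chow pair and 838 higher and 632 lower for atorvastatin on the diet against chow. There were 62 higher and 43 lower in both diet comparisons and 1466 higher and 973 lower in the difference between them. At 10 weeks the diet medians became bile acid transport and FXR -0.12 and male-biased liver genes -0.10. At 1 week they became lymphocyte markers -0.39 and circadian clock 0.16. With atorvastatin they became lymphocyte markers 0.067, chemokines, cytokines and adhesion 0.016, circadian clock -0.33 and red blood cell markers -1.38. With the floor at the 60th percentile, the genes past the rule numbered 127 higher and 143 lower for the diet at 10 weeks, 38 higher and 39 lower for the diet at 1 week, 59 higher and 58 lower for atorvastatin, 104 higher and 69 lower for the chow pair and 88 higher and 109 lower for atorvastatin on the diet against chow. There were 7 higher in both diet comparisons and 298 higher and 305 lower in the difference between them. The atorvastatin median of the 1-week diet genes was 0.12 for the higher set (percentile 97.9). At 10 weeks the diet medians became bile acid transport and FXR -0.12, MHC class II 0.38, cell cycle -0.52 and fat and pancreas markers 0.13. At 1 week they became sterol uptake and SREBP2 regulation -0.12 and MHC class II -0.21. With atorvastatin they became bile acid transport and FXR -0.16, MHC class II -0.18, extracellular matrix and fibrosis 0.080, unfolded protein response -0.17 and circadian clock -0.32. With a pseudocount in place of the floor, the genes past the rule numbered 208 higher and 165 lower for the diet at 10 weeks, 45 higher and 42 lower for the diet at 1 week, 107 higher and 113 lower for atorvastatin, 117 higher and 88 lower for the chow pair and 170 higher and 135 lower for atorvastatin on the diet against chow. There were 8 higher and 2 lower in both diet comparisons and 356 higher and 331 lower in the difference between them. The atorvastatin median of the 1-week diet genes was 0.13 for the higher set (percentile 98.6) and 0.085 for the lower set (percentile 91.6). At 10 weeks the diet medians became macrophage and Kupffer cell markers 0.52. At 1 week they became circadian clock 0.34. With the mean of all probe sets, the genes past the rule numbered 158 lower for the diet at 10 weeks, 64 lower for the diet at 1 week, 131 higher for atorvastatin, 133 higher and 108 lower for the chow pair and 183 higher and 122 lower for atorvastatin on the diet against chow. There were 457 higher and 357 lower in the difference between them. At 10 weeks the diet medians became bile acid synthesis -0.21, acute phase -0.065, complement and coagulation -0.078, lymphocyte markers 0.18, extracellular matrix and fibrosis 0.14, circadian clock 0.17 and small GTPases and prenylation 0.013. At 1 week they became bile acid transport and FXR -0.12, complement and coagulation 0.066, MHC class II -0.22, circadian clock 0.16 and mitochondrial respiration -0.091. With atorvastatin they became macrophage and Kupffer cell markers 0.33, chemokines, cytokines and adhesion 0.044, extracellular matrix and fibrosis 0.15 and small GTPases and prenylation 0.0075. Without the x and s probe sets, the list median became small GTPases and prenylation -0.063, for the diet at 10 weeks. Diet list medians at 1 week became MHC class II -0.21 and cell cycle -0.55. Atorvastatin list medians became lipoproteins 0.25 and small GTPases and prenylation -0.017. The log2 ratio turned to 0.26 for Ampd2 (atorvastatin), -0.44 for Dedd (the diet at 1 week), 0.89 for Mt1 (the diet at 10 weeks) and -0.26 for Samhd1 (the diet at 1 week). Under the 1.5-fold rule, the genes past the rule numbered 1270 higher and 1006 lower for the diet at 10 weeks, 554 higher and 677 lower for the diet at 1 week, 840 higher and 943 lower for atorvastatin, 979 higher and 805 lower for the chow pair and 1092 higher and 941 lower for atorvastatin on the diet against chow. There were 93 higher and 75 lower in both diet comparisons and 1864 higher and 1369 lower in the difference between them. Under the 3-fold rule, the genes past the rule numbered 48 higher and 42 lower for the diet at 10 weeks, 9 higher and 7 lower for the diet at 1 week, 27 higher and 32 lower for atorvastatin, 33 higher and 14 lower for the chow pair and 43 higher and 31 lower for atorvastatin on the diet against chow. There were 2 higher and 0 lower in both diet comparisons and 152 higher and 123 lower in the difference between them. The atorvastatin median of the 1-week diet genes was 0.12 for the higher set (percentile 79.3). With the mean of both chow arrays as reference, the genes past the rule numbered 167 lower for the diet at 10 weeks. Diet list medians at 10 weeks became cholesterol synthesis enzymes 0.63, sterol uptake and SREBP2 regulation 0.20, fatty acid and triglyceride synthesis 1.15, bile acid transport and FXR -0.12, PPAR alpha targets and fatty acid oxidation -0.13, lipoproteins -0.15, complement and coagulation -0.025, macrophage and Kupffer cell markers 0.38, chemokines, cytokines and adhesion -0.031, hepatocyte markers -0.19, xenobiotic metabolism 0.015, glutathione, NRF2 and metallothionein -0.22, fasting and glucose production 0.016 and male-biased liver genes -0.079. With the 1-week chow array as reference, the list medians became cholesterol synthesis enzymes 0.72, sterol uptake and SREBP2 regulation 0.079, bile acid transport and FXR -0.12, PPAR alpha targets and fatty acid oxidation -0.14, lipid droplet and fat storage 0.35, lipoproteins 0.083, complement and coagulation 0.070, macrophage and Kupffer cell markers 0.19, MHC class II 0.38, extracellular matrix and fibrosis 0.061, endothelial markers 0.086, hepatocyte markers 0.12, xenobiotic metabolism 0.16, glutathione, NRF2 and metallothionein -0.10, fasting and glucose production 0.18, male-biased liver genes 0.31 and mitochondrial respiration -0.087, for the diet at 10 weeks. The log2 ratio turned to 0.30 for Cyp51 (the diet at 10 weeks).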

Other observations

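Genes on the same side of both chow arrays on both 10-week diet arrays, with and without atorvastatin, were counted in an analysis chosen after seeing the data. At least 2-fold separated every diet array from every chow array for 17 higher and 17 lower genes. The higher genes with the largest smallest fold were Msmo1 (6.02-fold), Serpina12 (5.31-fold), Dbp (at least 5.16-fold), the squalene synthase gene Fdft1 (2.81-fold) and Stard4 (2.67-fold). The lower ones were Cdkn1a (3.32-fold), Fgf21 (3.16-fold), Pdk4 (3.15-fold), Rrs1 (at least 2.78-fold), Arntl (2.5-fold) and the heat shock gene Hspa1b (2.5-fold). Of the 15 ways to set 2 of these arrays against 2 others this one ranks 4, with 34 genes in all. The highest, 67 genes, sets both 10-week diet arrays against both 1-week arrays, and the 10-week chow and diet arrays against both 1-week arrays give 39.

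Lists not described so far had these medians for the diet at 10 weeks, all inside the central 95% of random lists. They were 0.09 for bile acid transport and FXR, where Nr0b2, a nuclear receptor that represses bile acid synthesis, had 1.10. Lipid droplet and fat storage had 0.04, with Fitm1 (1.60) and Mogat1 (1.39) higher and Plin5 (-1.60) and G0s2 (-1.15) lower. Acute phase had 0.05, complement and coagulation -0.20, chemokines, cytokines and adhesion 0.13, xenobiotic metabolism -0.21, unfolded protein response 0.05 and cell cycle 0.10 (-0.52 and apart with the floor at the 60th percentile). Fasting and glucose production had -0.15, small GTPases and prenylation 0.20, male-biased liver genes -0.43, female-biased liver genes 0.22, ribosomal proteins -0.05 and mitochondrial respiration 0.06. Of cholangiocyte markers 2 were measured, Krt23 and Krt19 (-0.58), too few for a percentile.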
